A study of Mus musculus with 48 samples.

How the data were processed

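RNA sequencing was done on 48 libraries of mouse Cas9-Hoxb8 cells, 3 in each of 16 groups. Per the labels' protocols, RNA was isolated with a PicoPure kit from cells sorted into extraction buffer, and libraries were made with an Illumina TruSeq kit. Per the series text, the libraries were read on a NovaSeq at the Functional Genomics Center Zurich, and mapping and counting used the SUSHI pipeline. The aligner, the counting program, its strand setting, the genome build and the annotation release are not given in the sources used here. The deposited table holds estimated counts per gene, which were taken to be the expected counts of a counting program because they are at least 0, are not all whole (58.1% lay within 0.01 of a whole number) and have totals that differ between libraries. The authors' own differential expression and gene set results were not analysed here.

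Library totals ran from 22.5 to 114 M counts with a median of 27.4 M. A count of 3 over all libraries of a group was used as the floor for genes with no counts in that group, and intervals and floors cover counting error only, since the reads carry no molecular identifiers. Within groups the lowest chi-square per degree of freedom was 2.4, so replicates varied more than counting error alone. Gene identifiers were matched to GENCODE M21, which is on the GRCm38 build, for chromosome, transcript length, GC share and biotype, and 25424 of 25528 genes (99.6%) had a match. Because the authors' build is not given, no coordinate from the deposited table was used with it. Only identifiers were compared.

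Counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter and the quasi-likelihood F test with 1 coefficient per group. The 36 libraries of the 12 genotype by treatment groups were fitted together (14059 genes, 24 residual degrees of freedom). The 12 transformed libraries were fitted with the 6 DMSO libraries of their genotypes (14403 genes, 12 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a contrast. Standard errors of log2 fold changes are the log2 fold change divided by the square root of its F statistic. Levels are counts per M counts (CPM, M for mega) on the TMM scale, given as mean and SD over 3 libraries. For the comparison of genotypes after transformation the 3 libraries of each clone were summed, so that clones were the replicates (15865 genes).

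There were 24 contrasts of libraries. For each genotype these were etoposide against DMSO and high cell density against DMSO. Genotypes were compared in DMSO, and the difference between genotypes in each response was tested as an interaction. Each transformed clone was compared with DMSO cells of its own genotype. In every contrast, 32 gene lists (stress responses, cell cycle and repair, metabolism, translation, blood lineages and leukaemia genes) were tested with camera from limma 3.58.1, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 32 lists. For each list the members called over all genes tested and the members called when adjusted over the list alone were both counted. Several lists share members, and progenitor, granule and mast cell lists hold genes that the studied cells express without treatment. A list call that was lost when camera estimated the correlation is marked with that adjusted p. The 32 lists, the contrasts, the tests and most alternatives were fixed before the data were examined.

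Genes named in the text follow a rule set at the same time. A panel (Ercc6l2, Trp53, Cdkn1a, Mdm2, Bbc3, Bax, Ccng1, Zmat3, Gdf15, Myc, Cebpa, Mpo, Elane and Kit) is always reported. Each pairwise contrast adds the 8 genes up and the 8 genes down with the largest log2 fold change among called genes with at least 5 CPM in the higher group and no overlap between the libraries. Each interaction adds 6 in each direction. Predicted models, small RNAs and pseudogenes were left out of these rankings. Lists add up to 4 called members each. Where a name lies outside this rule, the text says that it was chosen after its values were seen.

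Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a replicate block, fits on the groups of a contrast alone, leaving out each library in turn, and for the lists an estimated correlation, fry, the block and RLE factors. Per-library offsets for transcript length and for length with GC share, a fit without 2 transformed libraries over 60 M counts, and counts without chromosomes 1, 13 and 14 were chosen after the data were seen. Other splits of the 6 libraries of a pairwise contrast numbered 10, the real split included. For each interaction 40 relabellings of genotype within treatment were drawn with a fixed seed, the real labels included. The method was tested on simulated data. In wildtype libraries, 71.6% of genes given a 1.5-fold change, 82.1% of those given a 2-fold change and 92.4% of those given a 4-fold change were called, with 5 unchanged genes called among 14022 tested. For the etoposide interactions the shares were lower, 53.7%, 71.6% and 83.3% for E6l2-KO against wildtype and 62.7%, 68.7% and 81.8% for Trp53-KO against wildtype, with 2 and 6 unchanged genes called. For the comparison of clones these shares were 14.9%, 47.8% and 77.3%, with 21 unchanged genes called. A raised gene list was called in the simulation, as was 1 of 31 other lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.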

Results

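RNA was sequenced from Cas9-Hoxb8 cells, a mouse line of granulocyte and monocyte progenitors that is kept growing by a conditional Hoxb8 protein and carries Cas9 for gene editing. There were 4 genotypes: wildtype cells, cells edited for Ercc6l2 (E6l2-KO), cells edited for Trp53, the gene of p53 (Trp53-KO), and cells edited for both genes (E6l2-Trp53-KO). Each genotype was grown for 48 h in DMSO, the solvent control, in etoposide, a topoisomerase II poison that breaks DNA, or at high cell density. Wells held 0.25 M cells (M stands for mega), or 4 M at high density, and the etoposide concentration is not given in the sources used here. Cells labelled as etoposide transformed came from 4 clones, clones 4 and 6 of Trp53-KO and clones 7 and 12 of E6l2-Trp53-KO. The series text says that their RNA was taken without drug treatment beforehand. Each of the 16 groups had 3 libraries, 48 in all, and what separates the 3 libraries of a clone is not stated. The labels name no separately edited lines within a genotype of untransformed cells. Differences between genotypes therefore cannot be told apart from differences between edited lines. Totals were 22.5 to 40.9 M counts in the 36 libraries of untransformed cells and reached 114 M among transformed cells. Levels below are counts per M counts of the library (CPM), mean ± SD over n = 3 libraries, and a gene was called at an adjusted p under 0.05 over all genes tested. In all, 360 of 768 list tests were called with camera at its preset correlation and 72 of them also with an estimated correlation, so most list calls below rest on the preset value. Member counts are over all genes tested, followed by the count adjusted over the list alone where it differed.

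Levels of the edited genes are given for each group. Trp53 (ENSMUSG00000059552) mRNA stood at 79.1 ± 3.43 CPM in wildtype and 84.0 ± 3.48 CPM in E6l2-KO cells in DMSO, against 28.9 ± 0.628 CPM in Trp53-KO and 25.8 ± 0.595 CPM in E6l2-Trp53-KO cells. It was lower by a log2 fold change of -1.46 (SE 0.078, adjusted p = 8.38e-16) in Trp53-KO than in wildtype cells, with no overlap between the 3 libraries of each. With etoposide and at high density Trp53 was at 85.0 and 77.4 CPM in wildtype, 96.1 and 78.5 CPM in E6l2-KO, 28.3 and 25.4 CPM in Trp53-KO and 33.0 and 18.4 CPM in E6l2-Trp53-KO cells. Ercc6l2 (ENSMUSG00000021470), which encodes a helicase-like protein, had 31.3 ± 0.514 CPM in wildtype, 28.0 ± 1.33 CPM in E6l2-KO, 27.2 CPM in Trp53-KO and 28.0 CPM in E6l2-Trp53-KO cells in DMSO, and between 26.1 and 30 CPM in the 8 groups with etoposide or high density. The log2 difference between E6l2-KO and wildtype cells was -0.16 (SE 0.058, adjusted p = 0.124). Small edits can end a protein while the mRNA stays, so this level does not check the label. In the transformed clones, scaled with their own controls, Trp53 was at 13 ± 0.87 CPM in clone 4 and 11.3 ± 0.375 CPM in clone 6 against 27.4 ± 0.602 CPM in Trp53-KO cells in DMSO. Clones 7 and 12 had 36.8 ± 3.08 and 36.3 ± 2.61 CPM against 24.8 ± 0.603 CPM in E6l2-Trp53-KO cells in DMSO.

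**Figure D1:**
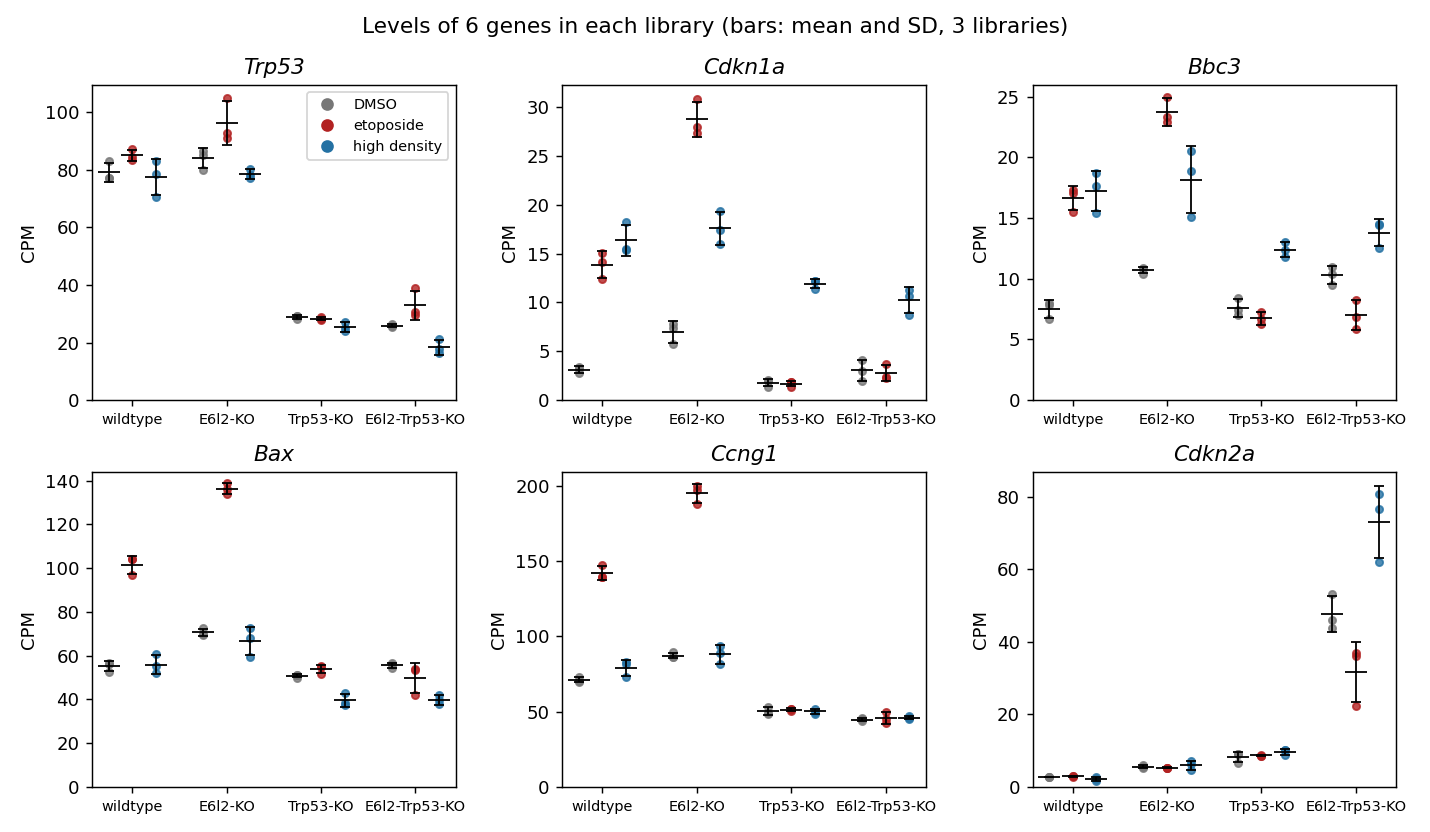
Levels in CPM (vertical axes, starting at 0) of Trp53, 4 p53 target genes and Cdkn2a in each library of untransformed cells, by genotype (horizontal axes) and treatment (colours), with black bars for mean and SD over 3 libraries. Cdkn1a reached 13.9 CPM in wildtype and 28.8 CPM in E6l2-KO cells under etoposide and stayed at 1.68 CPM in Trp53-KO cells, while Cdkn2a was highest in E6l2-Trp53-KO cells, at 47.6 CPM in DMSO.

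The first comparison asks what etoposide changes in wildtype cells, where both edited genes are intact. Cdkn1a (ENSMUSG00000023067), the p53 target that stops the cell cycle, rose 4.47-fold, from 3.11 ± 0.343 to 13.9 ± 1.35 CPM (log2 2.16, SE 0.17, adjusted p = 2.13e-11). Phlda3 (ENSMUSG00000041801), a p53 target that restrains Akt, rose 4.38-fold to 14.2 ± 0.51 CPM, and the proapoptotic Bbc3 (ENSMUSG00000002083) rose 2.22-fold to 16.6 ± 0.948 CPM. Ccng1 rose 1.99-fold and Bax 1.84-fold, whereas Mdm2, which degrades p53, stood at 44.0 ± 1.05 against 42.7 ± 0.575 CPM (adjusted p = 0.515). The lactate exporter Slc16a3 (ENSMUSG00000025161) fell from 29.8 ± 4.27 to 8.0 ± 0.444 CPM, and the immediate early gene Egr1 from 5.78 ± 1.34 to 1.12 ± 0.172 CPM. Exosc6 (ENSMUSG00000109941), a subunit of the RNA exosome, had the largest fold among the named genes, 19.8-fold, from a control level of 0.558 ± 0.884 CPM that varied between libraries.

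Of 36 p53 targets tested in wildtype cells, 19 rose, 2 fell and 15 were not called (20 up and 3 down when adjusted over the list alone). The list was called up (camera adjusted p = 1.68e-14, and 1.58e-06 with an estimated correlation). Of 32 interferon response genes, 13 rose and 1 fell, a list call that also held (0.000194, and 0.0408 with an estimated correlation). Hypoxia and glycolysis genes went down, 21 of 32 with 1 up (1.87e-08, adjusted p = 0.109 with an estimated correlation), Ak4 and Ankrd37 among them at log2 fold changes of -1.96 and -1.49. In cholesterol synthesis 20 of 24 genes rose (adjusted p = 0.242 with an estimated correlation). Ribosomal protein genes rose in 39 of 40 cases (0.108 with an estimated correlation) and respiratory chain genes in 33 of 35 (0.0521). DNA repair genes leaned down, 14 of 40 with 3 up (0.0366, and 0.361 with an estimated correlation), Palb2 among them by -0.31. S phase genes were called in neither direction, 3 up and 4 down of 40 (adjusted p = 0.939). All 40 ribosomal protein genes rose adjusted over the list alone, and 1 S phase gene rose and 3 fell.

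Across all genes, 5830 of 14059 were called in wildtype cells, 2860 up and 2970 down. Changes of at least 2-fold were mostly losses, 1313 down against 51 up. The share of counts on transcripts of unknown coding status (TEC) fell from a mean of 0.339% to 0.168%, and ribosomal protein genes took 16.9% of counts against 14.1%. The wildtype DMSO share was the highest of the untransformed groups, against 0.237% to 0.292% for other genotypes in DMSO. Trp53-KO against wildtype cells in DMSO also had mostly losses of at least 2-fold (277 down, 42 up). So did E6l2-KO against wildtype cells in DMSO (108 down, 30 up), and etoposide in E6l2-KO cells with their own control (648 down, 56 up). In wildtype, E6l2-KO, Trp53-KO and E6l2-Trp53-KO cells the TEC share in DMSO was 0.339%, 0.292%, 0.248% and 0.237%. In that order, losses of at least 2-fold numbered 1313, 648, 0 and 12 with etoposide (gains 51, 56, 0 and 109). At high density losses numbered 781, 291, 175 and 172 (gains 423, 358, 450 and 438). How far the DMSO controls carry the losses was not tested. Log2 fold changes went with transcript length across genes (Spearman -0.32) and with GC share (0.36), though genes are not independent replicates. With an offset for length and GC, 3530 of the 5830 calls remained and 103 turned to the opposite direction.

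In E6l2-KO cells the same comparison asks whether loss of Ercc6l2 changes the response to DNA breaks. Cdkn1a rose 4.12-fold, from 6.98 ± 1.12 to 28.8 ± 1.79 CPM, Phlda3 4.68-fold to 24 ± 1.78 CPM and Ccng1 2.24-fold to 195 ± 6.22 CPM. Trp53inp1, a p53 target that promotes cell death, rose 2.36-fold to 80.3 ± 0.571 CPM, and Mdm2 1.28-fold to 54.0 ± 1.43 CPM (adjusted p = 3.64e-06). Genes against oxidative stress moved together, with 18 of 19 NRF2 targets up (19 adjusted over the list alone), among them Nqo1 (ENSMUSG00000003849) by 1.26, Osgin1 by 1.16 and Hmox1 (ENSMUSG00000005413) by 1.10 on the log2 scale. Polr2a, the large subunit of RNA polymerase II, fell from 72.2 ± 4.86 to 29.4 ± 0.396 CPM, and Slc16a3 fell to 8.04 ± 0.106 CPM.

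Of the p53 targets in E6l2-KO cells 24 rose, 2 fell and 10 were not called (3.41e-28, and 2.07e-09 with an estimated correlation). The NRF2 call held as well (8.96e-15, and 0.000719). Hypoxia and glycolysis genes went down, 18 of 32, with none up, respiratory chain genes up in 31 of 35, apoptosis genes up in 9 of 22 and mature neutrophil genes up in 7 of 18, each at 0.0446 with an estimated correlation. Ribosomal protein genes rose in 39 of 40 cases (adjusted p = 0.257 with an estimated correlation), and 17 of 40 DNA repair genes fell (0.00144, and 0.174 with an estimated correlation). Adjusted over the list alone, 20 hypoxia and glycolysis genes and 18 DNA repair genes fell and 33 respiratory chain genes rose. In all 4918 genes were called, 2653 up and 2265 down. Fold changes went with transcript length (Spearman -0.28) and GC share (0.29) across genes, and with the length and GC offset 3130 of these calls remained in the same direction and 22 turned. Of the 3787 genes called in wildtype and E6l2-KO cells alike, 3784 went the same way, and the log2 fold changes correlated across genes (Pearson r = 0.73).

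The difference between those responses was tested directly, and 2 genes were called, with 1021 at an unadjusted p under 0.05. Tfec, a transcription factor of the Mitf family, went from 22.8 ± 1.78 to 34.2 ± 1.33 CPM in E6l2-KO cells and from 31.4 ± 2.29 to 29.5 ± 0.765 CPM in wildtype cells (interaction log2 0.67, SE 0.12, adjusted p = 0.0345). Ptgds, a prostaglandin synthase, went from 18.2 ± 3.33 to 28.7 ± 0.743 CPM in E6l2-KO against 20.5 ± 2.16 to 64.1 ± 3.32 CPM in wildtype cells (-0.98, SE 0.14, adjusted p = 0.000722). The Tfec call ended with the length offset and in 10 of 12 fits that left out 1 library, with values between 0.59 and 0.73, while Ptgds stayed called. DESeq2 called 20 genes, edgeR without a count filter 58 and edgeR on these 12 libraries alone 201. Cdkn1a (-0.12, adjusted p = 0.953) and Mdm2 (0.31, adjusted p = 0.13) were not called. No p53 target was called, 1 when adjusted over the list alone, with a list p of 0.0482 and 0.198 with an estimated correlation. Cholesterol synthesis genes had a lower response in E6l2-KO cells as a list, with none of 24 called over all genes and 22 lower when adjusted over the list alone. Their median interaction was -0.331 (5.95e-31, and 0.0206 with an estimated correlation), and Lss at -0.56 and Acat2 at -0.43 were examples.

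Trp53-KO cells were treated in the same way to ask which part of the response needs p53. Cdkn1a was at 1.68 ± 0.284 CPM with etoposide against 1.78 ± 0.373 CPM in DMSO, Bbc3 at 6.74 ± 0.513 against 7.62 CPM and Ccng1 at 51.1 ± 0.933 against 50.1 CPM. No gene was called with edgeR at an adjusted p under 0.05 (lowest 0.491), 468 had an unadjusted p under 0.05, DESeq2 called 0, edgeR without a count filter 16 and edgeR on these 6 libraries alone 1. None of the 36 p53 targets was called (list adjusted p = 0.547). Lists were nonetheless called without a called member. Interferon, mature neutrophil and mast cell genes leaned up (each 0.0132 with an estimated correlation), and hypoxia and glycolysis genes leaned down with a median log2 fold change of -0.11 (1.17e-11, and 0.0457 with an estimated correlation). Adjusted over the list alone, 3 mast cell genes and 1 mature neutrophil gene were called.

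Between Trp53-KO and wildtype cells the etoposide response differed for 3257 genes, 1697 higher and 1560 lower, of which 1795 remained in the same direction with the length and GC offset and 5 turned. Differences of at least 2-fold were mostly higher, 944 against 21 lower. Wildtype cells alone had 1313 losses of that size against their DMSO control, and how far that control carries the difference was not tested. The interaction was -2.22 for Cdkn1a (SE 0.31, adjusted p = 8.19e-06), -2.20 for Phlda3 (adjusted p = 3.95e-08), -1.32 for Bbc3, -0.96 for Ccng1 (adjusted p = 3.53e-10) and -0.80 for Bax. Slc16a3 had 1.48 (adjusted p = 9.38e-06) and Egr1 2.32 (SE 0.65, adjusted p = 0.00984), and both fell in wildtype cells. Of 36 p53 targets 14 were lower, 1 higher and 21 not called (16 lower and 1 higher adjusted over the list alone), and this was the only list of 32 whose call held with an estimated correlation (2.03e-10, and 3.02e-05). Ribosomal protein genes were lower in 38 of 40 cases (adjusted p = 0.179 with an estimated correlation), cholesterol synthesis genes in 18 of 24 (0.163) and respiratory chain genes in 26 of 35 (0.109), the latter pair in 19 and 30 cases adjusted over the list alone. The olfactory and vomeronasal receptor genes Olfr839, Olfr639 and Vmn2r53 were also among the highest, and their reads can be shared with near-identical genes, so these values are uncertain.

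**Figure D2:**
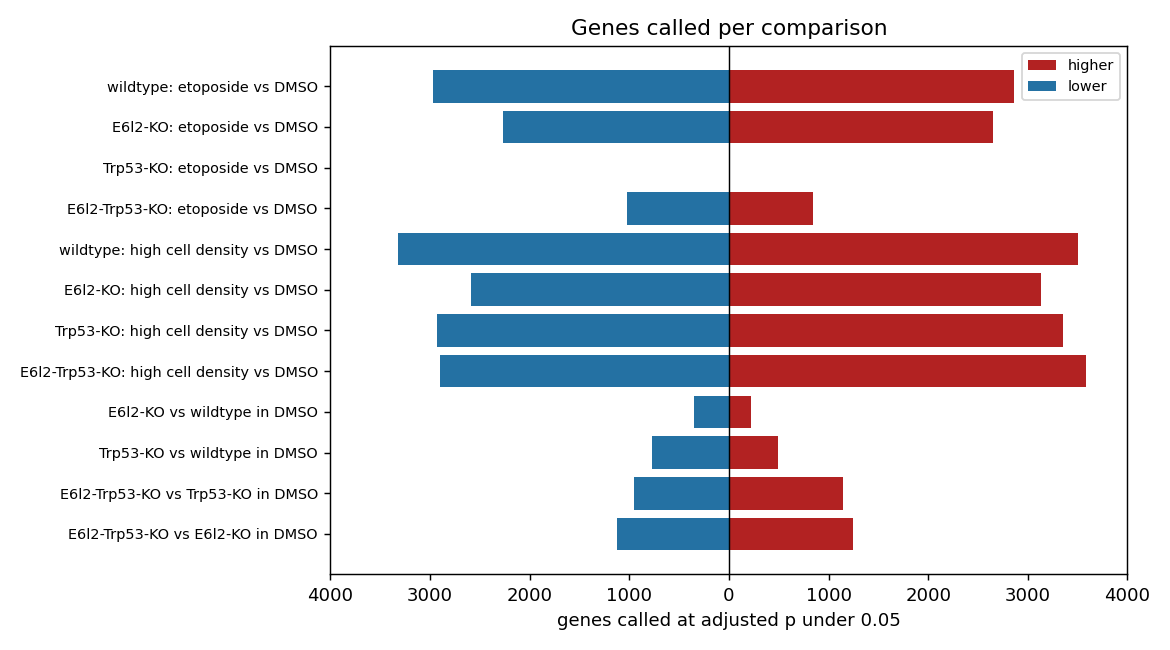
Number of genes called at an adjusted p under 0.05 (horizontal axis; higher to the right in red, lower to the left in blue) in the 12 comparisons of untransformed cells (vertical axis), 3 libraries per group. Etoposide gave 5830 calls in wildtype and 0 in Trp53-KO cells, and high density at least 5724 in each genotype.

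E6l2-Trp53-KO cells, which lack p53 as well, had 1858 genes called under etoposide, 839 up and 1019 down. Thbs1 (ENSMUSG00000040152), a secreted matrix protein, rose 2.91-fold, from 11.8 ± 1.0 to 34.5 ± 2.41 CPM, and the glutathione transferase Mgst2 2.06-fold. Glycolysis genes fell, the phosphofructokinase Pfkl from 219 ± 18.4 to 106 ± 21.9 CPM, Slc16a3 from 37.6 ± 7.63 to 14 ± 2.39 CPM and the mitophagy gene Bnip3 from 105 ± 11.6 to 52.4 ± 7.09 CPM. Cdkn1a stood at 2.79 ± 0.814 against 3.05 CPM (adjusted p = 0.807), while Bbc3 fell by 0.59 on the log2 scale (adjusted p = 0.000641) and Trp53 rose by 0.37 (adjusted p = 0.0031), or by 0.19 and no longer called without etoposide replicate 3. The fit of these 6 libraries alone called neither of the latter pair. Hypoxia and glycolysis genes went down in 22 of 32 cases with 1 up (3.21e-37, and 0.0004 with an estimated correlation) and cholesterol synthesis genes in 21 of 24 (0.0114 with an estimated correlation). Interferon genes went up in 11 of 32 cases, mature neutrophil genes in 8 of 18 and monocyte genes in 7 of 21, at 0.0004, 0.00284 and 0.0332 with an estimated correlation. Unfolded protein and integrated stress response genes fell in 20 of 34 cases (adjusted p = 0.0694 with an estimated correlation), and p53 targets were not called as a list (3 up, 4 down, 29 not called, 0.849). Adjusted over the list alone, 25 hypoxia and glycolysis, 23 cholesterol synthesis and 23 unfolded protein genes fell, 16 interferon and 8 monocyte genes rose, and 5 p53 targets rose and 4 fell.

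The count of 1858 depended on single libraries. It was 546 without etoposide replicate 3, 1142 without DMSO replicate 2, 2850 without etoposide replicate 2 and 2902 without etoposide replicate 1, and a fit of these 6 libraries alone called 118. Etoposide replicate 3 stood apart from its group, with 40.9 M counts against 25.6 and 23.5 M, 14302 genes with at least 10 counts against 13055 and 12970, and a chi-square per degree of freedom of 46.6 and 48.5 against replicates 1 and 2, which had 4.45 between them. Without it the median size of the 1858 log2 fold changes went from 0.28 to 0.20 while their median SE stayed near 0.07 (0.074 before), and 1854 kept their direction. These genes were chosen by the full fit, which shares the other libraries, so most directions would be kept in any case. Thbs1, Pfkl, Slc16a3, Bnip3 and Mgst2 were still called without replicate 3. Of 889 genes called in wildtype and E6l2-Trp53-KO cells alike, 644 went opposite ways (Pearson r = -0.35 across genes). Log2 fold changes went with GC share at a Spearman correlation of -0.32 across genes in E6l2-Trp53-KO cells, against 0.36 in wildtype cells, and with the length and GC offset 1284 of the 1858 calls remained in the same direction. Against E6l2-Trp53-KO cells in DMSO, with a TEC share of 0.237%, the etoposide libraries had 0.29%, a rise where wildtype and E6l2-KO cells had falls.

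Whether Ercc6l2 loss matters without p53 was read from the difference between E6l2-Trp53-KO and Trp53-KO responses, called for 29 genes (13 higher, 16 lower, 1920 at an unadjusted p under 0.05). The highest was Thbs1 (1.32, SE 0.2, adjusted p = 0.00182), which in Trp53-KO cells went from 26.9 ± 3.36 to 31.4 ± 4.04 CPM. Slc16a3 (-1.02, adjusted p = 0.0187), Pfkl (-0.81, adjusted p = 0.00454), Bnip3 (-0.76) and the enolase Eno1 (-0.64) were lower. Of the hypoxia and glycolysis genes 8 of 32 were lower and none higher (17 and 1 adjusted over the list alone), with list values of 1.78e-21 and 0.0179 with an estimated correlation. The interferon list was higher with 1 called member (0.000403, and 0.0496 with an estimated correlation). None of 36 p53 targets was called (0.566). The 29 became 311 without E6l2-Trp53-KO etoposide replicate 1 and 6 without E6l2-Trp53-KO DMSO replicate 2, and a fit of the 12 libraries alone called 2. Of the 29 themselves, 6 remained called without E6l2-Trp53-KO etoposide replicate 3 and 5 without Trp53-KO etoposide replicate 3.

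Between E6l2-Trp53-KO and E6l2-KO cells, which differ in Trp53, 4875 genes had a different etoposide response, 2259 higher and 2616 lower. At 2-fold or more 1067 were higher and 47 lower, and how far the DMSO controls carry this was not tested. With the length and GC offset 2628 of the 4875 remained in the same direction and 34 turned. Phlda3 (-2.41, adjusted p = 2.25e-11), Cdkn1a (-2.13), Bbc3 (-1.74), Ccng1 (-1.13, adjusted p = 2.98e-12) and Bax (-1.11) were lower, as was the adenylate kinase Ak1 (-2.48). Of the p53 targets 19 of 36 were lower and 2 higher (20 and 2 adjusted over the list alone, 2.08e-13, and 5.35e-06 with an estimated correlation). NRF2 targets were lower in 16 of 19 cases (9.08e-11, and 0.00535 with an estimated correlation), with Ftl1 at -1.10 and Hmox1 at -1.06. The highest values, 9.18 for Rps27 (SE 1.6) and 3.32 for H2bc23, are uncertain. Rps27 stood at 419 ± 354 CPM in etoposide and 16.5 ± 4.38 CPM in DMSO in E6l2-Trp53-KO cells while its near copy Rps27rt moved the other way, and H2bc23 and H2bc24 did likewise.

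High cell density was the other stress applied, without a drug. Cdkn1a rose in each genotype, 5.25-fold to 16.4 ± 1.59 CPM in wildtype, 2.52-fold to 17.6 ± 1.72 CPM in E6l2-KO, 6.80-fold to 11.9 ± 0.442 CPM in Trp53-KO and 3.33-fold to 10.2 ± 1.36 CPM in E6l2-Trp53-KO cells. Egfl7 (ENSMUSG00000026921), a secreted vascular protein that hosts a microRNA, rose 8.0-fold to 104 ± 9.02 CPM in wildtype and 7.45-fold to 146 ± 10.7 CPM in E6l2-Trp53-KO cells. Myc (ENSMUSG00000022346) rose 1.67-, 1.57-, 1.42- and 1.47-fold in wildtype, E6l2-KO, Trp53-KO and E6l2-Trp53-KO cells. The scaffold gene Shank3 fell by 2.32, 2.07, 2.45 and 2.34 on the log2 scale, and neutrophil elastase, Elane (ENSMUSG00000020125), by 1.25, 1.45, 1.16 and 0.74 in the same order. Bax was at 55.9 ± 4.51 against 55.2 ± 2.16 CPM in wildtype cells (adjusted p = 0.866), and it fell by 0.36 in Trp53-KO and 0.48 in E6l2-Trp53-KO cells. With the length and GC offset it was called lower in wildtype cells too (log2 -0.29, adjusted p = 6.98e-05).

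Hypoxia and glycolysis genes rose in 30, 30, 29 and 26 of 32 cases in wildtype, E6l2-KO, Trp53-KO and E6l2-Trp53-KO cells (0.023, 0.0113, 0.0341 and 0.146 with an estimated correlation). Interferon genes rose in 14, 16, 18 and 20 of 32 cases (0.0403, 0.0368, 0.0958 and 0.0227). Immediate early genes rose in 18, 19, 17 and 13 of 23 (0.0403, 0.0433, 0.103 and 0.365). Dendritic cell genes rose in 5 of 11 in each genotype, H2-Ab1 and Bst2 among them (0.023, 0.0191, 0.0341 and 0.0227). Genes of the unfolded protein and integrated stress response rose in 26, 25, 18 and 10 of 34 (adjusted p = 0.097, 0.125 and 0.485 with an estimated correlation in wildtype, E6l2-KO and Trp53-KO cells), and the last was not called as a list (0.681). Ribosomal protein genes rose in at least 39 of 40 in each genotype, which the estimated correlation left uncalled (0.116, 0.128, 0.219 and 0.221), and they took 17.8% of counts in wildtype cells. S phase genes fell in 23, 26, 34 and 29 of 40 (adjusted p = 0.303, 0.246, 0.146 and 0.221 with an estimated correlation). G2/M genes fell in 34, 29, 33 and 15 of 40, and 5 rose in E6l2-Trp53-KO cells, calls that were lost with an estimated correlation (adjusted p = 0.116, 0.206, 0.151 and 0.515). The p53 targets were mixed, with 16 up and 5 down of 36 in wildtype (0.0126, adjusted p = 0.0601 with an estimated correlation), and 15 and 6, 13 and 10, 17 and 9 in the others (0.126, 0.272 and 0.309). Adjusted over the list alone, 30 hypoxia and glycolysis genes rose in Trp53-KO cells, 21 interferon genes in E6l2-Trp53-KO cells, 19 immediate early genes in wildtype cells, and 26 and 19 unfolded protein genes in E6l2-KO and Trp53-KO cells. In the same way S phase genes fell in 26, 28, 34 and 30 cases, G2/M genes fell in 35, 30, 33 and 15 cases, and p53 targets were 14 up in Trp53-KO and 10 down in E6l2-Trp53-KO cells.

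High density gave 6823 calls in wildtype (3504 up, 3319 down; 5211 remained and 32 turned with the length and GC offset), 5724 in E6l2-KO (3132 up, 2592 down), 6288 in Trp53-KO (3356 up, 2932 down) and 6490 in E6l2-Trp53-KO cells (3586 up, 2904 down). Of 4771 genes called in wildtype and E6l2-KO cells 4769 went the same way, as did 4546 of 4551 shared with Trp53-KO and 4384 of 4431 shared with E6l2-Trp53-KO cells. Few genes differed between genotypes in this response. E6l2-KO against wildtype called 1 gene (611 at an unadjusted p under 0.05, DESeq2 2), the calmodulin-like gene Calml4 (ENSMUSG00000032246; 2.07, SE 0.37, adjusted p = 0.0462), which went from 6.8 ± 0.855 to 15.3 ± 2.04 CPM in E6l2-KO cells and was at 0.538 ± 0.132 and 0.285 ± 0.1 CPM in wildtype cells. That call ended with replicate as a block, with the length offset, in the fit of these 12 libraries alone and in 8 of 12 fits that left out 1 library. The p53 targets had a median interaction of -0.0797 with no member called, 1 lower adjusted over the list alone, and a list p of 0.00202, which held at 0.0218 with an estimated correlation. Cdkn1a had -1.06 (adjusted p = 0.169).

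Trp53-KO against wildtype called 13 genes in the density response (8 higher, 5 lower, 2025 at an unadjusted p under 0.05), of which 3 remained with the length and GC offset. The glutathione-degrading Chac1 (-0.78) and the endotoxin receptor Cd14 (-0.72, adjusted p = 0.0101) were lower and Csmd1 (0.87) was higher. Unfolded protein and integrated stress response genes responded less, 1 of 34 called and 20 lower adjusted over the list alone (5.11e-16, adjusted p = 0.236 with an estimated correlation). E6l2-Trp53-KO against Trp53-KO called 47 (36 higher, 11 lower). The interferon-inducible Ifi209 (1.64, adjusted p = 0.00439) went from 5.16 ± 0.611 to 10.5 ± 2.11 CPM in E6l2-Trp53-KO and from 2.05 ± 0.242 to 1.32 ± 0.211 CPM in Trp53-KO cells, and the secreted inhibitor Wfdc17 had 1.24 (adjusted p = 0.000202). Erythroid genes were higher as a list with none called over all genes and 3 adjusted over the list alone (0.000374, and 0.0403 with an estimated correlation). E6l2-Trp53-KO against E6l2-KO called 192 (98 higher, 94 lower), with the stress pseudokinase Trib3 (-1.54, adjusted p = 0.00384) and the cystine carrier Slc7a11 (-0.98) lower. The unfolded protein and integrated stress response was lower in 9 of 34 members, and in 24 adjusted over the list alone (1.6e-26, and 0.0302 with an estimated correlation). Leaving out 1 library at a time moved the 13 between 0 and 73, the 47 between 19 and 180 and the 192 between 72 and 353.

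In DMSO the genotypes were compared without added stress. E6l2-KO cells had 569 genes called against wildtype, 219 up and 350 down. Calml4 was 12.7-fold higher at 6.8 ± 0.855 CPM, and Limch1 (ENSMUSG00000037736), an actin-binding gene, 5.06-fold higher at 26.0 ± 1.66 CPM. Cdkn1a was 2.24-fold higher (6.98 ± 1.12 against 3.11 ± 0.343 CPM, adjusted p = 2.2e-05), Bbc3 1.43-fold, Bax 1.28-fold and Ccng1 1.23-fold. Of 36 p53 targets 10 were higher and 1 lower (11 and 1 adjusted over the list alone, 5.39e-06, and 0.00145 with an estimated correlation). B cell genes were lower in 4 of 11 cases, with Cd79b at -0.92 and Igll1 at -0.87 (1.98e-06, and 0.0133 with an estimated correlation). The coagulation inhibitor Tfpi was at 6.17 ± 0.462 against 26.5 ± 2.75 CPM. Changes went with GC share across genes (Spearman 0.40), 426 of the 569 calls remained in the same direction with the length and GC offset, and a fit of these 6 libraries alone called 943.

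Trp53-KO cells in DMSO had 1269 genes called against wildtype, 497 up and 772 down, which became 635 without wildtype DMSO replicate 2 and 830 without Trp53-KO DMSO replicate 3. Changes went with GC share across genes (Spearman 0.38), and 811 of the 1269 calls remained in the same direction with the length and GC offset. Limch1 was higher again, 7.9-fold at 40.7 ± 1.92 CPM, and Tfpi was down to 1.07 ± 0.178 CPM. The tetraspanin Cd63 (ENSMUSG00000025351) was at 35.7 ± 3.91 against 101 ± 5.36 CPM. Of the p53 targets 7 were lower and 1 higher of 36 (0.0118, adjusted p = 0.0652 with an estimated correlation), Cdkn1a at -0.82 (adjusted p = 0.0171) and Ccng1 at -0.51. Mature neutrophil genes were higher in 7 of 18 cases, S100a8 by 3.93 and S100a9 by 3.60 on the log2 scale, and monocyte genes in 9 of 21, and both held with an estimated correlation (0.00447 and 0.0197), as did NF-kB targets with 3 of 17 higher (0.0414). More were higher, 9 mature neutrophil genes and 7 NF-kB targets, when adjusted over the list alone.

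Against Trp53-KO cells, E6l2-Trp53-KO cells in DMSO had 2098 genes called, 1144 up and 954 down. The kinase Pim2 (ENSMUSG00000031155) was 9.81-fold higher at 66.2 ± 9.72 CPM. Cdkn2a (ENSMUSG00000044303), which encodes p16 and the p53 activator p19Arf, was at 47.6 ± 4.94 against 8.28 ± 1.44 CPM (log2 2.52, adjusted p = 1.11e-15). It was singled out after its values were seen in this comparison. Tfpi was at 23.9 ± 3.84 CPM, near the 26.5 CPM of wildtype cells, and Elane fell by 1.47. Primary granule genes were lower in 12 of 19 cases, erythroid genes higher in 6 of 11, megakaryocyte genes in 7 of 11 and mast cell genes in 7 of 14, and these calls held with an estimated correlation (0.0157, 0.00128, 0.0127 and 0.011). Against E6l2-KO cells 2367 genes were called, 1248 up and 1119 down, with Pim2 10.3-fold and Cdkn2a 8.54-fold higher. There, 12 of 36 p53 targets were lower and 3 higher (0.00129, and 0.00851 with an estimated correlation), granule genes were lower in 12 of 19 cases (0.0084) and B cell genes higher in 8 of 11 (0.00619). Adjusted over the list alone, 13 granule genes were lower and 1 higher against Trp53-KO cells, and 6 p53 targets and 9 B cell genes were higher against E6l2-KO cells. Of 294 genes called both for E6l2-KO against wildtype and for E6l2-Trp53-KO against Trp53-KO cells, 172 went the same way (Pearson r = 0.051 across genes).

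**Figure D3:**
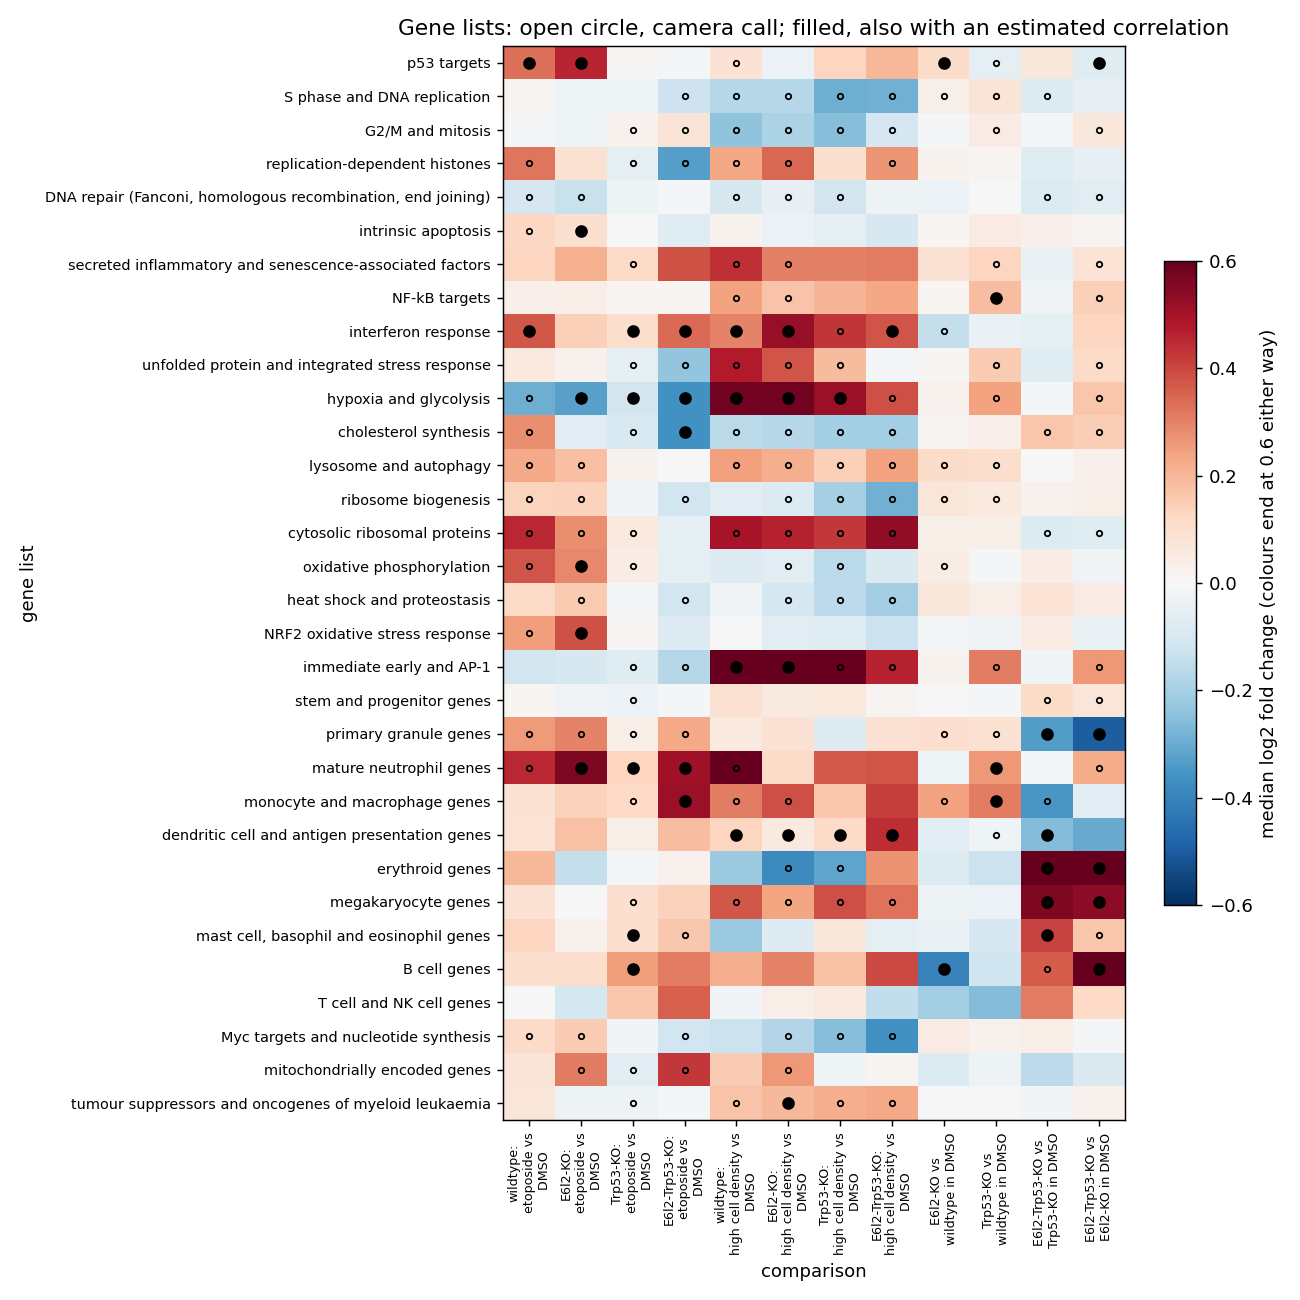
Median log2 fold change of the members of each of 32 gene lists (vertical axis) in the 12 comparisons of untransformed cells (horizontal axis), as colours that end at 0.6 either way, with an open circle for a camera call and a filled one for a call that also held with an estimated correlation. The p53 targets have filled circles for etoposide in wildtype (median 0.332) and E6l2-KO cells and none in Trp53-KO cells.

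The transformed clones were compared with DMSO cells of their own genotype to describe how they differed. No culture time or number of cells seeded was available for the clones. Transformation therefore cannot be told apart from culture conditions in these differences. Proteases stored in mast cell granules were among the most abundant transcripts. Cpa3 (ENSMUSG00000001865), the mast cell carboxypeptidase, stood at 38700, 40600, 35600 and 33400 CPM in clones 4, 6, 7 and 12, against 1130 CPM in Trp53-KO and 1660 CPM in E6l2-Trp53-KO cells in DMSO. The tryptase Tpsb2 (ENSMUSG00000033825) was at 34200 ± 1460 CPM in clone 4 with 1 count over the 3 control libraries, a ratio of 2850000 with a counting interval of 511000 to 1.13e+08. The chymase Cma1 (ENSMUSG00000022225) was at 70800 ± 3620 CPM in clone 7 against 1.08 ± 0.505 CPM. These proteases have close relatives, so the split of reads among Tpsb2, Cma1, Mcpt4 and similar genes is uncertain. Fcer1a (ENSMUSG00000005339), a chain of the IgE receptor, had 2000 ± 105 CPM in clone 4 and 2390 ± 153 CPM in clone 6 and no counts in Trp53-KO controls, at least 54100- and 66300-fold higher against a floor of 3 counts over the group. Clones 7 and 12 had 66.6 and 172 CPM of it. The stem cell factor receptor Kit (ENSMUSG00000005672) was at 2690 ± 39.5, 2340 ± 57.1, 2430 ± 68.8 and 2510 ± 102 CPM against 302 ± 6.67 and 337 ± 6.62 CPM, and the transcription factor Gata2 (ENSMUSG00000015053) between 609 and 762 CPM against 49.1 and 60.5 CPM.

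Myeloperoxidase, Mpo (ENSMUSG00000009350), was at 19.1 ± 1.22, 0.964 ± 0.153, 6.22 ± 0.727 and 65.3 ± 3.8 CPM in clones 4, 6, 7 and 12 against 2290 and 1860 CPM in DMSO. Cebpa (ENSMUSG00000034957), a transcription factor of granulocyte fate, was between 0.208 and 8.33 CPM against 201 and 191 CPM. Elane was the exception in clone 12, with 15.3 ± 1.81 against 11.1 ± 2.07 CPM (log2 0.47). Myc was at 22 to 31.8 CPM against 174 and 157 CPM. The cytokine receptor Flt3 was 3620-fold lower in clone 4 and 4430-fold lower in clone 12. Among p53 targets Zmat3 (ENSMUSG00000027663) was at 19.3, 17.8, 17.7 and 16.6 CPM against 0.802 and 1.08 CPM, Bbc3 at 50.7, 49.8, 34.2 and 34.4 CPM against 7.24 and 9.9 CPM, and Cdkn1a between 11.2 and 13.2 CPM against 1.69 and 2.93 CPM. The list itself was split, with 21 up and 13 down of 37 in clone 4 and 18 up and 15 down in clone 12, and it was not called in any clone (0.646, 0.708, 0.696 and 0.494).

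**Figure D4:**
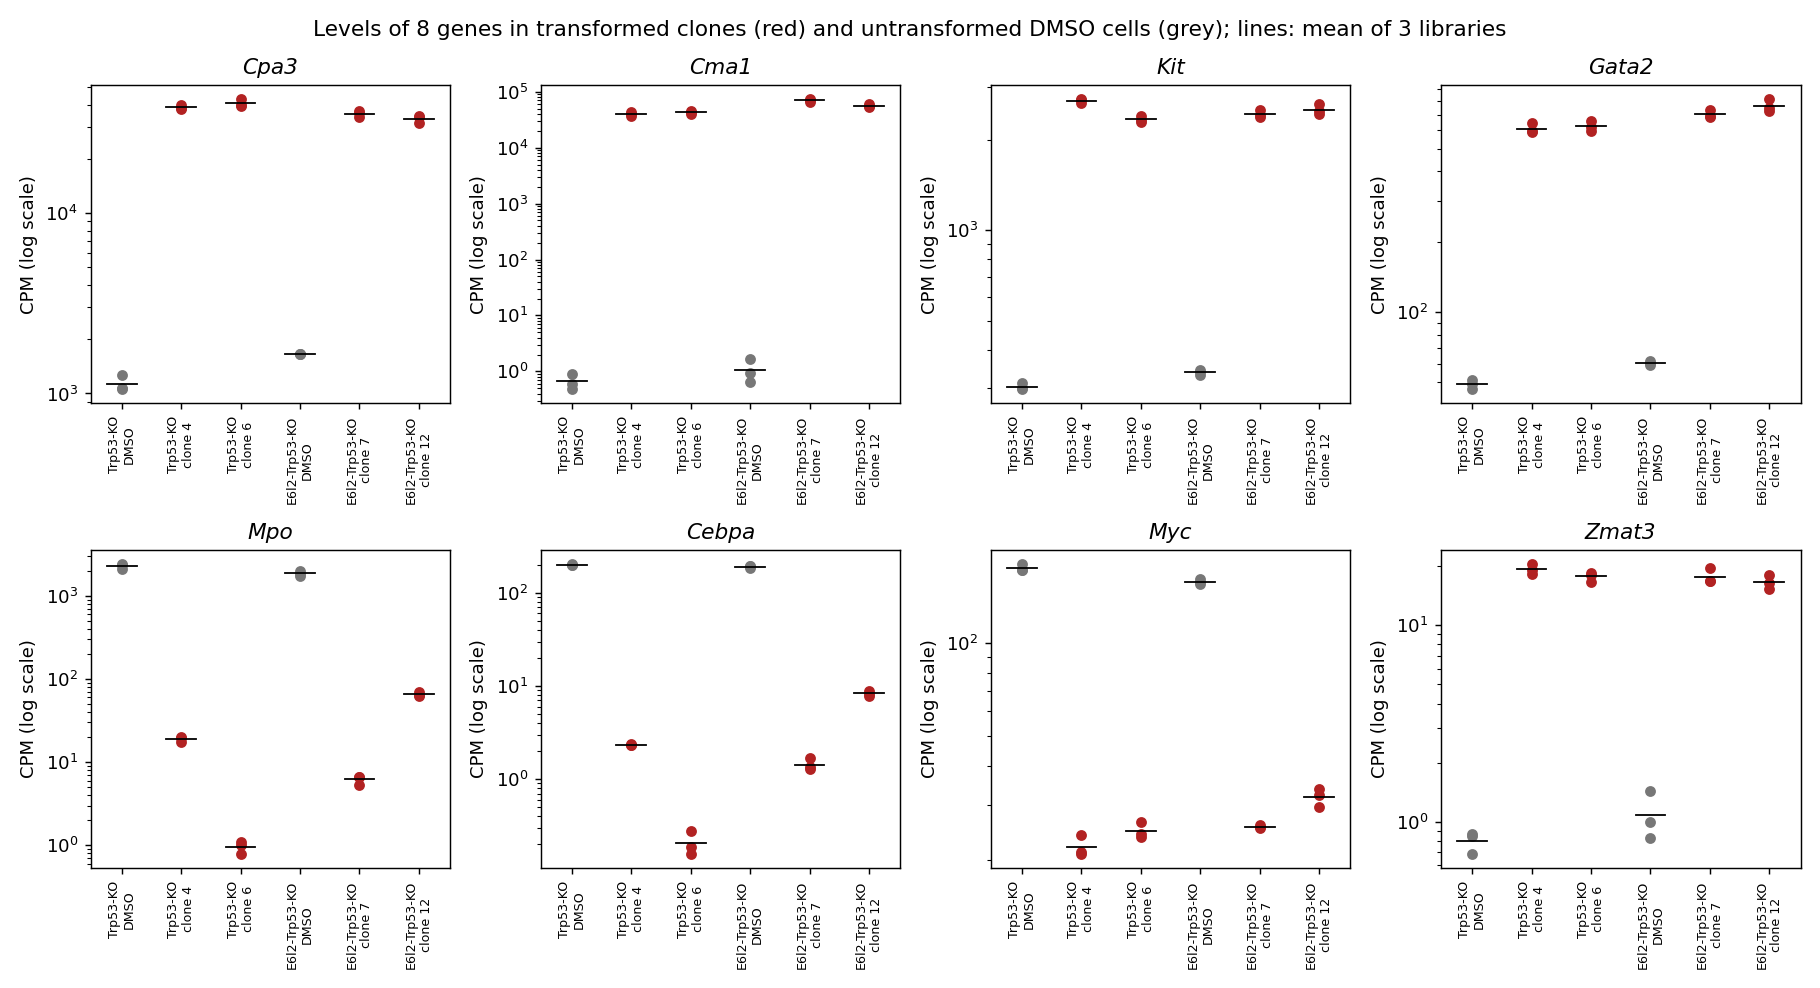
Levels in CPM (vertical axes, log scale) of 8 genes in each library of the 4 transformed clones (red) and of DMSO cells of the same genotypes (grey), along the horizontal axes, with lines for means of 3 libraries. Cpa3 and Kit were higher in each clone, with Kit from 2340 to 2690 CPM, and Mpo and Cebpa lower, with Cebpa at 8.33 CPM at most.

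Mast cell genes rose in 16 of 20 cases in each clone and fell in 3, 4, 4 and 4 (0.000556, 0.000526, 0.000878 and 0.0224 with an estimated correlation for clones 4, 6, 7 and 12). Myc targets fell in 22 of 25 in each (0.0432, 0.017, 0.0218 and 0.0224). Ribosome biogenesis genes fell in 34 of 35 in clone 4 and in all 35 in the other clones (0.0616, 0.0218, 0.0378 and 0.0224). Primary granule genes fell in 15, 15, 16 and 14 of 19 (0.0616, 0.0215, 0.0429 and 0.197). Stem and progenitor genes fell in 17 of 23 in each, Hoxa9 among them (0.0616, 0.0364, 0.101 and 0.109), and S phase genes in 38, 36, 37 and 39 of 40 (0.0972, 0.104, 0.101 and 0.0818). Lysosome genes rose in 32, 30, 30 and 31 of 35, likewise lost with an estimated correlation (adjusted p = 0.0616, 0.104, 0.101 and 0.089), with 31 in clone 7 adjusted over the list alone. All 40 ribosomal protein genes fell in each clone, a call lost with an estimated correlation (adjusted p = 0.707, 0.772, 0.6 and 0.439), and their share of counts was 5.71% to 7.46%. The 10 most abundant genes of a library took 17.3% to 20.4% of counts on average, against 5.62% to 6.24% in untransformed groups. For a few lists median, mean and test differed in sign. In clone 4, NRF2 targets had a median of -0.199, a mean of 0.346 and a test downward, and unfolded protein genes a median of -0.0174, a mean of 0.174 and a test upward.

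Calls numbered 11583 of 14403 genes in clone 4 (6009 up, 5574 down), 11158 in clone 6 (5550 up, 5608 down), 11451 in clone 7 (5846 up, 5605 down) and 11483 in clone 12 (5818 up, 5665 down). Of 9969 genes called in clones 4 and 7, which share no control libraries, 9126 went the same way (Pearson r = 0.86 across genes), and 8973 of 9798 in clones 6 and 12. The 3 libraries of a clone measure that clone, and whether both clones of a genotype share an origin is not stated. One library of clone 12, replicate 3 with 114 M counts, had a TEC share of 0.817%. Its chi-square per degree of freedom was 73.5 and 61.8 against replicates 1 and 2, which had 9.31 between them.

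With clones as the replicates, 2 against 2, 4623 of 15865 genes differed between E6l2-Trp53-KO and Trp53-KO clones, 2426 up and 2197 down. Replicate 3 of clone 12 held most of the summed counts of that clone, 114 M beside 25.7 and 28.6 M. Without the 2 libraries over 60 M counts, this one and replicate 3 of clone 4, 4416 of the 4623 calls remained in the same direction. Leaving out a clone gave 2199 without clone 7, 2299 without clone 12, 2702 without clone 4 and 3571 without clone 6, each from 2 clones against 1, so that the spread comes from the other genotype alone. Cd63 was at 652 and 691 CPM in clones 7 and 12 against 1.94 and 0.961 CPM in clones 4 and 6 (log2 8.81, SE 0.36, adjusted p = 0.000695). The transcription factor Sox4 (ENSMUSG00000076431, chromosome 13) was at 152 and 177 against 1.64 and 0.76 CPM. The heparan sulfate sulfotransferase Hs6st2 (ENSMUSG00000062184, chromosome X) went the other way, at 1.71 and 1.67 against 542 and 490 CPM (log2 -8.26, SE 0.12, adjusted p = 6.53e-05), and the prion protein gene Prnp was at 0.186 and 0.386 against 55.0 and 109 CPM. Chromosomes 1, 13 and 14 held 392, 365 and 249 of the genes called, 21.8% together. That share was not set against their share of all genes tested, so it does not measure an excess on them.

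Expression also shifted by chromosome. Relative to all genes, the median log2 fold change on chromosome 13 was -0.922 in clone 4 and -0.876 in clone 6, and that on chromosome 1 was 0.336 and 0.235. Clones 7 and 12 had 0.489 and 0.368 on chromosome 14. In the comparisons of untransformed cells, chromosome medians lay between -0.0898 and 0.105. Ercc6l2 lies on chromosome 13, and its own log2 fold change was 0.11 in clone 4 (adjusted p = 0.106), 0.51 in clone 6, 0.68 in clone 7 and 0.64 in clone 12.

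**Figure D5:**
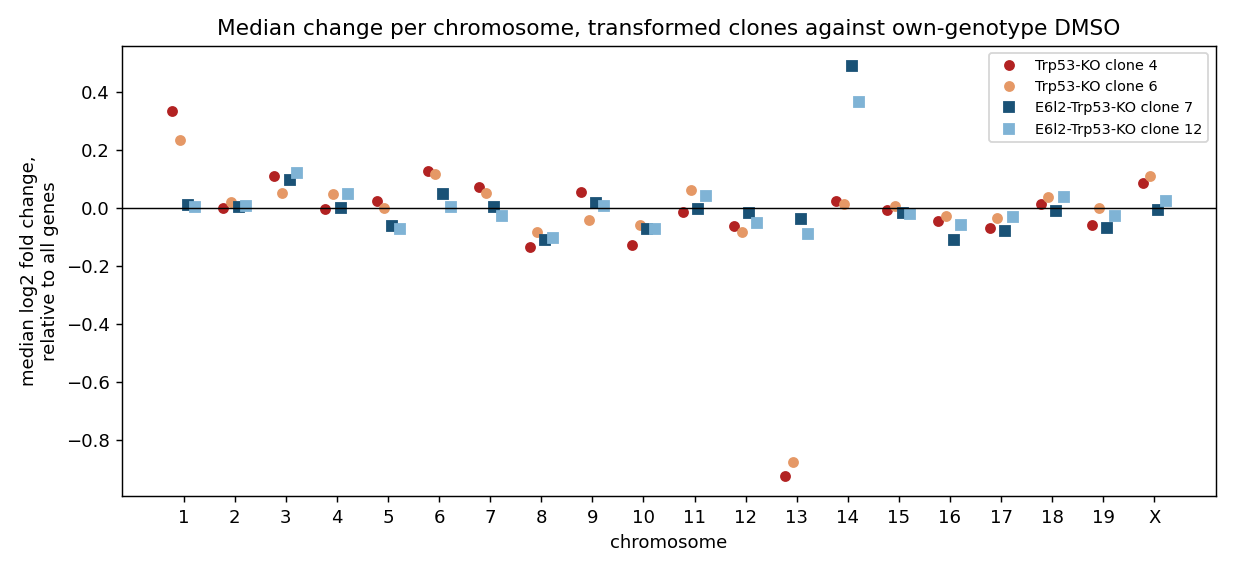
Median log2 fold change of the genes on each chromosome relative to all genes (vertical axis), by chromosome (horizontal axis), in the 4 transformed clones against DMSO cells of their own genotype, 1 point per clone. Chromosome 13 was lowest in clones 4 and 6, at -0.922 and -0.876, and chromosome 14 highest in clones 7 and 12, at 0.489 and 0.368.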

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

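The results here are differences between genotypes in their response to the same treatment, each from a test of the difference itself. Naming the 2 genes furthest in each direction and the lists called with both correlations was chosen after the list results were seen. The tests of untreated libraries in Trp53-KO and of fewer cells per well in E6l2-Trp53-KO were also chosen after the result was seen.

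In the etoposide response, E6l2-KO and wildtype cells differed in 2 genes, Tfec at 0.673 and Ptgds at -0.977 on the log2 scale. List medians were -0.143 for the interferon response and -0.331 for cholesterol synthesis. Trp53-KO and wildtype cells differed in 3257 genes, with Egr1 at 2.32, Olfr839 at 2.12 (uncertain, as a receptor gene with near copies), Cdkn1a at -2.22 and Phlda3 at -2.2, and a median of -0.247 for p53 targets. Between E6l2-Trp53-KO and Trp53-KO cells 29 genes differed, with Thbs1 at 1.32, mt-Nd5 at 0.874, Slc16a3 at -1.02 and Pfkl at -0.814. The mt-Nd5 value is uncertain, since the mean mitochondrial share of E6l2-Trp53-KO libraries was 2.61% in etoposide (2.99% in replicate 3) against 2.1% in DMSO, and the call ended without that replicate. Medians there were 0.184 for the interferon response and -0.251 for hypoxia and glycolysis. E6l2-Trp53-KO and E6l2-KO cells differed in 4875 genes, with Ak1 at -2.48 and Phlda3 at -2.41, and medians of -0.483 for p53 targets and -0.4 for NRF2 targets. The values 9.18 for Rps27 and 3.32 for H2bc23 are uncertain because their near copies moved the other way.

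In the response to high density, 1 gene differed between E6l2-KO and wildtype cells, Calml4 at 2.07, and p53 targets had a median of -0.0797. Trp53-KO and wildtype cells differed in 13 genes, with Csmd1 at 0.868, Mbd5 at 0.409, Chac1 at -0.78 and Cd14 at -0.715. Between E6l2-Trp53-KO and Trp53-KO cells 47 genes differed, with Ifi209 at 1.64, Wfdc17 at 1.24, Htr1b at -1.12, Trem1 at -0.857 and a median of 0.462 for erythroid genes. E6l2-Trp53-KO and E6l2-KO cells differed in 192 genes, with Gsap at 1.25, Trib3 at -1.54, Fam78b at -1.34 and Hbb-bt at 1.59, a globin gene whose near copies make it uncertain. The unfolded protein and integrated stress response had a median of -0.329.

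Genotypes were also relabelled within treatments, 40 ways in all with the real labels, in fits of the 12 libraries alone, whose counts differ from those above. For etoposide the real labels gave 201 genes for E6l2-KO against wildtype (highest other 122), 4430 for Trp53-KO against wildtype (3681), 2 for E6l2-Trp53-KO against Trp53-KO (22) and 3817 for E6l2-Trp53-KO against E6l2-KO (2720). As many genes came from 1, 1, 2 and 1 of the 40 ways. For high density the real labels gave 0, 11, 21 and 78 genes in the same order and the highest others 1041, 143, 3835 and 888, with as many from 40, 2, 4 and 3 ways. Several of these are many times the real count. Relabelling within a treatment can turn a difference between genotypes into an apparent interaction, so such counts need not point to a further structure of the samples. Other sources were not tested. At high density replicate 1 had the lowest mitochondrial share in all 4 genotypes (1.99%, 1.93%, 1.88% and 1.73%), and the relabellings took no account of that. Because the relabelled sets mix genotypes that already differed in DMSO, by 569, 1269, 2098 and 2367 genes in the same order, they are no even match for the real labels. The bound set beforehand for these splits therefore decides nothing, and whether chance is excluded stays open for all 8 counts.

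Trp53-KO cells had 0 genes called for etoposide with edgeR, with 468 at an unadjusted p under 0.05 and 0 with DESeq2, which untreated libraries under the etoposide label might give. Lists were nonetheless called, 19 of 32, 5 of them also with an estimated correlation. The lists were not tested on other splits of the 6 libraries, so these calls do not decide the question. In the density response of E6l2-KO against wildtype cells, with 1 gene called, 8 lists were called and 1 held. Medians of hypoxia and glycolysis (-0.111), interferon (0.104) and mature neutrophil genes (0.128) had the directions seen in E6l2-Trp53-KO cells (-0.365, 0.338 and 0.508). The others of the 5 lists are not compared here. Across all 14059 genes, Trp53-KO fold changes had r = 0.14 with those of E6l2-Trp53-KO cells. Over the 1858 genes called in E6l2-Trp53-KO cells r was 0.59. That was the highest of 20 signed splits of the 6 Trp53-KO libraries, of which 1 was as high and the next had 0.42. A drug effect shared by both genotypes would give that, but 20 splits are too few for a share under 0.05, so untreated libraries and a response lost with p53 cannot be told apart. The biological explanation that the design names, loss of Trp53, stays open.

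The 1858 genes called for etoposide in E6l2-Trp53-KO cells had technical and biological explanations. A trend with transcript length is argued against, since 88.9% of the calls remained in the same direction after a length offset, but the trend with GC share was larger (Spearman -0.32 against 0.12 for length, across genes) and 1284 of the 1858 calls remained with both offset. A single library, etoposide replicate 3, could carry much of the count, because without it 26.6% of the calls remained, between the bounds of 10% and 50% set beforehand, it had the highest total of its group (40.9 M), and the median size of the 1858 log2 changes fell from 0.283 to 0.198. Fewer cells per well than in DMSO are another candidate explanation, since 55.8% of the 995 genes shared with the wildtype density response moved the opposite way, 555 against 452 from independent lists. Among genes with the largest changes that share was 73% for the real split and 71.8% for the highest other of 20. Hypoxia and glycolysis genes rose at high density in wildtype cells and fell with etoposide here, whereas interferon genes rose in both. Fewer cells per well thus stay open too, beside the effect of losing both genes. Hypoxia and glycolysis genes also fell with etoposide in wildtype and E6l2-KO cells, where fewer cells per well were not tested as an explanation.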

How the results depend on the processing

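The offsets for transcript length and for length with GC share, the fit without 2 transformed libraries over 60 M counts and the counts without chromosomes 1, 13 and 14 were alternatives chosen after the data were seen. Few interaction genes, 3 libraries per group and camera's preset correlation limit what follows, and where a value moved or reversed the cause was not tested. Depth limits genes near the floor, such as those at 1 count or none in controls.

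With DESeq2 the etoposide interactions moved from 2 to 20 genes (E6l2-KO against wildtype) and from 29 to 74 (E6l2-Trp53-KO against Trp53-KO). The density interactions moved from 1 to 2 (E6l2-KO against wildtype), from 13 to 60 (Trp53-KO against wildtype) and from 47 to 72 (E6l2-Trp53-KO against Trp53-KO). Without a count filter these 5 became 58, 228, 3, 232 and 112, the density interaction of E6l2-Trp53-KO against E6l2-KO went from 192 to 302, and etoposide in Trp53-KO cells gave 16. Fits of the contrast's own groups gave 1 gene for etoposide in Trp53-KO, 118 in E6l2-Trp53-KO and 943 for E6l2-KO against wildtype in DMSO. Such fits gave 201 and 2 for the etoposide interactions of 2 and 29 genes, and 0, 21 and 78 for the density interactions of 1, 47 and 192. The length offset gave 1 gene for E6l2-KO against wildtype under etoposide, and 0 and 5 for the density interactions of 1 and 13. The length and GC offset gave 15 for the first, 5 for the density interaction of 13 and 324 for that of 192.

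Replicate numbers were read as names only, since no contrast had all its same-number pairs correlated above 0.1. Across the high density groups, though, pairs of replicate 1 had a mean of 0.24 (0.088 to 0.44), against 0.043 and 0.096 for replicates 2 and 3. All 4 libraries of replicate 1 correlated best with their own number, against 2 and 3 of 4, and had the lowest mitochondrial share of their group. A set of libraries shared by these groups may lie behind that, which stays open. With a replicate block the etoposide interaction of 29 gave 49, and the density interactions of 1 and 13 gave 0 and 39.

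Leaving out each library in turn gave 546 to 2902 genes for etoposide in E6l2-Trp53-KO cells, lowest without etoposide replicate 3 and highest without etoposide replicate 1, with 2850 without etoposide replicate 2 and 1142 without DMSO replicate 2. Trp53-KO against wildtype in DMSO had 635 to 1327, lowest without wildtype DMSO replicate 2 and 830 without Trp53-KO DMSO replicate 3. The etoposide interactions of 2 and 29 had 1 to 4 and 6 to 311, and the density interactions 0 to 1, 0 to 73, 19 to 180 and 72 to 353. Between transformed genotypes the count of 4623 went to 2199 to 3571 without 1 clone, where the spread comes from the other genotype alone, and to 8572 with the 12 libraries as replicates. RLE size factors and the fit without 2 libraries over 60 M counts kept each count of genes within 1.5 times. Dropping the calls on chromosomes 1, 13 and 14 did so too, but without a new fit. Those calls were 21.8% of the 4623, too few to pass that bound, so this shows no robustness to chromosome shifts. The other counts without 1 library stayed within 1.5 times, such as 4810 to 5945 for etoposide in wildtype and 11126 to 11524 for clone 4.

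Of the 360 list calls 72 were called with an estimated correlation. The direction of 1 list reversed, mature neutrophil genes in clone 12 under fry from limma (adjusted p = 0.00196). Under the length and GC offset 12 named values reversed. In wildtype etoposide these were Ccne2 (0.256), Dclre1c (0.0463), Pbx3 (0.112), Lmo2 (-0.00595), Meis1 (0.0362) and mt-Nd4 (0.198), and in E6l2-KO etoposide Ccne2 (0.19) and Tcf4 (0.000628). Bax in wildtype at high density had -0.294. Among interactions these were Ccne2 in Trp53-KO against wildtype under etoposide (-0.247), Tcf4 in E6l2-Trp53-KO against E6l2-KO under etoposide (-0.0442) and Rgs18 in Trp53-KO against wildtype at high density (-0.0707). Of 1772 named values under that offset 1552 kept direction and call, and of 2355 under DESeq2 2281 did, with none reversed. Without 1 library at a time 15074 of 16500 did, with none reversed, though these fits share most libraries with the full fit. A length trend may add to the wildtype etoposide calls, yet 78.6% of them remained in the same direction after the length offset.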

Other observations

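The tests of chromosome shifts below were chosen after the shifts were seen, and for copy number the shares per stretch had not been looked at when the bound was set. Some values go beyond a single comparison above. Cdkn2a differed by genotype in DMSO, from 2.67 ± 0.0743 CPM in wildtype through 5.57 ± 0.369 CPM in E6l2-KO and 8.28 ± 1.44 CPM in Trp53-KO to 47.6 ± 4.94 CPM in E6l2-Trp53-KO cells. At high density it stood at 73.0 ± 9.84 CPM in E6l2-Trp53-KO cells and at 2.17 ± 0.485 CPM in wildtype cells. In transformed cells, on their own scale, it was at 15.5 ± 2.32 and 14.8 ± 0.42 CPM in clones 4 and 6 and at 20.9 ± 1.12 and 23 ± 1.7 CPM in clones 7 and 12, so that the latter lay below their untransformed control of 45.7 ± 4.52 CPM and the former above theirs of 7.87 ± 1.31 CPM. Gdf15, a stress cytokine and p53 target, was at 15.6 ± 0.955 CPM in clone 7 and 9.05 ± 1.0 CPM in clone 12 against 2.02 ± 0.239 CPM in clone 4 and 3.89 ± 0.297 CPM in clone 6.

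At high density platelet factor 4, Pf4, rose by 1.17, 1.19, 0.80 and 1.19 on the log2 scale in wildtype, E6l2-KO, Trp53-KO and E6l2-Trp53-KO cells, while the surrogate light chain gene Igll1 fell by 1.09, 0.66, 1.04 and 1.23. As lists, megakaryocyte genes were called up (0.0366, 0.0393, 0.0443 and 0.0259), which an estimated correlation left uncalled (0.184, 0.211, 0.238 and 0.231). B cell genes (0.587, 0.15, 0.629 and 0.173) and primary granule genes (0.979, 0.483, 0.199 and 0.666) were not called. Mpo was at 2850 ± 75.2 CPM in wildtype cells at high density against 2260 ± 89.6 CPM in DMSO, where Elane was at 10.8 ± 0.603 against 25.8 ± 1.63 CPM. The checkpoint receptor Pdcd1 was at 8.25 ± 2.87 CPM in E6l2-Trp53-KO cells at high density against 0.151 ± 0.0654 CPM in DMSO. The granule protease gene Gzmb had no counts in controls and was at least 20800-, 68400- and 61300-fold higher in clones 6, 7 and 12, and clone 4 had the lowest level, 292 ± 2.75 CPM.

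For pairwise comparisons the 6 libraries can be split in 10 ways, too few for a share under 0.05, so only the real count and the highest other are given. For etoposide these were 6436 and 0 in wildtype, 5845 and 0 in E6l2-KO, 1 and 5 in Trp53-KO (4 of 10 as many) and 118 and 0 in E6l2-Trp53-KO cells. High density gave 6658 and 1, 5839 and 0, 6322 and 0, and 6162 and 0 in the same order. In DMSO they were 943 and 1 for E6l2-KO and 1716 and 1 for Trp53-KO against wildtype, then 2259 and 2 for E6l2-Trp53-KO against Trp53-KO and 2808 and 0 against E6l2-KO. The clones gave 11219, 10694, 11118 and 11038 for clones 4, 6, 7 and 12, with 0 as the highest other in each. In all but Trp53-KO with etoposide 1 of 10 splits, the real one, gave as many.

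A candidate explanation for the lower median of chromosome 13 in clones 4 and 6 is loss of a chromosome copy, set against a mast cell programme that happens to use few of its genes. A mast cell programme shared by all 4 clones is argued against for the chromosome as a whole. Clones 7 and 12 also expressed mast cell proteases, and their chromosome 13 shift reached at most a ratio of 0.095 to that of clone 4. Between the clones of the 2 genotypes 4623 genes differed, and Fcer1a was lower in clones 7 and 12. A programme particular to clones 4 and 6 therefore stays open. In 1 stretch of 20 Mb, at -1.07 in clone 4, clones 7 and 12 had medians of -0.39 and -0.669, so the argument against a shared programme does not cover it. Their other stretches with at least 20 genes had medians from -0.187 to 0.258. For copy number, a share of at least 80% of genes below the median was required beforehand in each stretch of 20 Mb. The lowest stretch in clone 4 had 66.1%, with a median of -0.565. The next stretches with at least 20 genes had shares of 71.5%, 81.6%, 80.4%, 83.1% and 71.8%. Their medians were -1.07, -1.01, -0.791, -1.06 and -1.0. In clone 6 the shares in the same order, the first stretch included, were 74.6%, 77.1%, 85.1%, 79.5%, 85.9% and 76.9%. Several stretches of each clone were thus below 80%. Copy number may explain part of the shift, and it stays open because RNA levels alone do not count chromosomes and the DNA was not analysed here. Both clones of a genotype carried the same shifts, which could also mean that they are not independent.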
